A study of Homo sapiens with 58 samples.

How the data were processed

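RNA was measured by RNA sequencing in 58 libraries from 2 human cancer cell lines, MCF-7 (breast) and OVCAR-8 (ovary), grown for 7 or 14 days in 4 kinds of culture. The deposited files are 4 tables of raw read counts per gene, 1 for each line and day, with 57820 genes in each and no gene filter. Per the labels' protocols, total RNA was isolated with RNeasy columns. Per the labels, 7-day OVCAR-8 libraries were made with a TruSeq Stranded mRNA kit and all others with the Illumina NeoPrep system. The submitters' processing notes name Trimmomatic, FastQC, STAR and featureCounts, without versions or settings, and the hg19 genome. Neither the notes nor the labels state whether strand was used in counting, so values of overlapping and antisense genes are uncertain, as are those of genes with near-identical copies. Ensembl identifiers and symbols are those of the files. No hg19 annotation was at hand, so no coordinates are given. Gene types were matched by identifier to GENCODE v29 for 90.52% of the genes.

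The total per library was between 15.58 and 75.09 M counts. Replicates of a group differed by more than counting error, with a chi-square per gene of at least 2.202, so the errors given are spreads between libraries. Counting intervals and floors cover counting error only. The p-values measure the spread between these libraries, and the labels do not say whether replicates came from separately started cultures. Where a group had 0 counts of a gene in all its libraries, the fold is a lower bound against a floor of 3 counts over the group. With 1 to 3 counts, the ratio has a 95% interval from the counts. CPM stands for counts scaled to a common library total, ± for the SD between libraries beside a CPM, and SE for the standard error of a log2 fold change.

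The comparisons, tests, gene lists and rule for naming genes were set before the data were examined. All calculations used R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and the data.table package, version 1.17.8, and figures Python 3.11.15 with matplotlib 3.10.9 and pandas 2.3.3. Within each table, genes passing filterByExpr were scaled by TMM and fitted with the 4 cultures as groups, without a replicate term. Each contrast was tested with edgeR's robust quasi-likelihood test. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. In each table the 3 cultures in Matrigel were compared with 2D and with each other. Whether a contrast differed between the lines was tested as the OVCAR-8 effect minus the MCF-7 effect, in 1 edgeR fit of both tables of a day. At day 7 the kit differs between the lines, and in OVCAR-8 between the days. Calls shared by a pair of tables were compared with independent lists by a one-sided Fisher's exact test for each direction.

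In all, 27 gene lists were fixed. They cover targets of hypoxia-inducible factor (HIF), glycolysis and glucose transport, nuclear genes of oxidative phosphorylation, mitosis, DNA replication, cholesterol biosynthesis, the unfolded protein response, ATF4 targets, interferon-stimulated genes, NF-kB and inflammatory cytokines, extracellular matrix, epithelial adhesion and keratins, mesenchymal genes, YAP and SRF targets, immediate early genes, p53 targets, estrogen receptor targets, metallothioneins, stem-like cell markers, replication-dependent histones, mitochondrially encoded genes and ribosomal proteins. The other lists hold markers of the MCF-7 line, the OVCAR-8 line, fibroblasts, immune cells and endothelium. Lists with at least 3 tested genes were tested against the other genes with limma's camera on voom values, with a preset correlation of 0.01 and adjustment over the lists of a contrast. Each camera value is an adjusted p, and a call is given with that under an estimated correlation. Counts of list members refer to adjustment over all genes, and the count adjusted over the list alone stands beside it where it differed.

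Named genes were chosen by rule from those called with a mean of at least 10 CPM in the higher culture, with every library of one culture above every library of the other. Symbols with the pattern of clone, antisense, LINC, small RNA or histone genes, XIST and Y-linked genes were left out. The 3 with the largest log2 fold change in each direction were taken for Matrigel at 21% oxygen against 2D, 3% against 21% and gradient against 21%, and the 2 largest for the other contrasts. From each list described, up to 4 called members with the smallest p were taken, or up to 2 where none was called. CA9, NDRG1, VEGFA, SLC2A1, MKI67 and HMGCS1 were always followed. For shared calls and for differences between lines, 5 genes in each direction were taken.

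The alternatives were RLE size factors in place of TMM, DESeq2's Wald test, no filter on low counts, a replicate block, leaving out each library in turn and, for camera, an estimated correlation. Leaving out all libraries numbered 4 in 7-day MCF-7, or all numbered 1 in 14-day OVCAR-8, was added after the data were seen. Whether replicate numbers pair libraries was checked by correlating same-numbered libraries' deviations from their group means. In 7-day MCF-7 every pair among the Matrigel cultures exceeded 0.1, with a range of 0.1229 to 0.7116. The numbers were taken as pairs, but not in the main fits. The labels give no shared batch or day, so that pairing comes from the data. In each other contrast the lowest same-number correlation was under 0.1.

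The steps were tested on simulated counts for 3% against 21% oxygen, with 200 changed genes. In 7-day MCF-7 (16095 genes), edgeR recovered 56 of 99 genes changed 2-fold and 88 of 100 changed 4-fold, with 10 unchanged genes called. In 14-day MCF-7 (16525 genes) it recovered 85 of 100 and 95 of 98, with 11. In 7-day OVCAR-8 (16600 genes) it recovered 95 of 100 and 100 of 100, with 14. In 14-day OVCAR-8 (17066 genes) it recovered 76 of 100 and 95 of 100, with 3. The test of the difference between lines recovered 49 of 98 and 78 of 100 at day 7 (18413 genes), and 54 of 98 and 86 of 100 at day 14 (19054 genes). In each table camera recovered a list raised 1.5-fold, and in 7-day MCF-7 it also called 1 unchanged list. Reads were not analysed here. All 58 libraries were used.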

Results

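RNA was sequenced from 58 cultures of MCF-7, an invasive ductal carcinoma line of the breast, and OVCAR-8, a high-grade serous ovarian line. Cells grew for 7 or 14 days in flasks (2D) at 21% oxygen, or in 3 mg/mL Matrigel (3D), a basement membrane gel, at 3% oxygen, at 21% oxygen or in a bioreactor that sets up an oxygen gradient. These make 16 groups. Of them 12 have n = 4. The 7-day MCF-7 3D 21% group and the 14-day OVCAR-8 3D 3% group have n = 3, and the 14-day MCF-7 3D 3% and gradient groups have n = 2. Counts per library were 19.61 to 37.26 M in 7-day MCF-7, 28.38 to 75.09 in 14-day MCF-7, 15.58 to 24.19 in 7-day OVCAR-8 and 21.9 to 50.32 in 14-day OVCAR-8. The first principal component took 47.32%, 77.74%, 72.22% and 54.82% of the variance in these tables, in the same order. Fold changes below are log2 values. The genes followed throughout are CA9 (ENSG00000107159.8), a carbonic anhydrase, NDRG1 (ENSG00000104419.10), a stress response gene, VEGFA (ENSG00000112715.16), an angiogenic growth factor, SLC2A1 (ENSG00000117394.15), a glucose transporter, MKI67 (ENSG00000148773.8), a proliferation marker, and HMGCS1 (ENSG00000112972.10), an enzyme of sterol synthesis.

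Markers of each line were higher in that line than in the other. Summed MCF-7 line markers were 11500 to 24600 CPM in the 8 MCF-7 groups and 180 to 459 CPM in the 8 OVCAR-8 groups. Summed OVCAR-8 line markers were 4730 to 8260 CPM in OVCAR-8 and 160 to 1020 CPM in MCF-7. Immune cell markers summed to at most 3.34 CPM in any group mean and endothelial markers to at most 13.9 CPM. Fibroblast markers ranged from 1.85 to 61 CPM. In 14-day MCF-7 they were 1.85 ± 0.415 CPM in 2D and 51.2 ± 9.93 CPM in 3D at 21% oxygen, moving with the extracellular matrix genes described next.

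**Figure D1:**
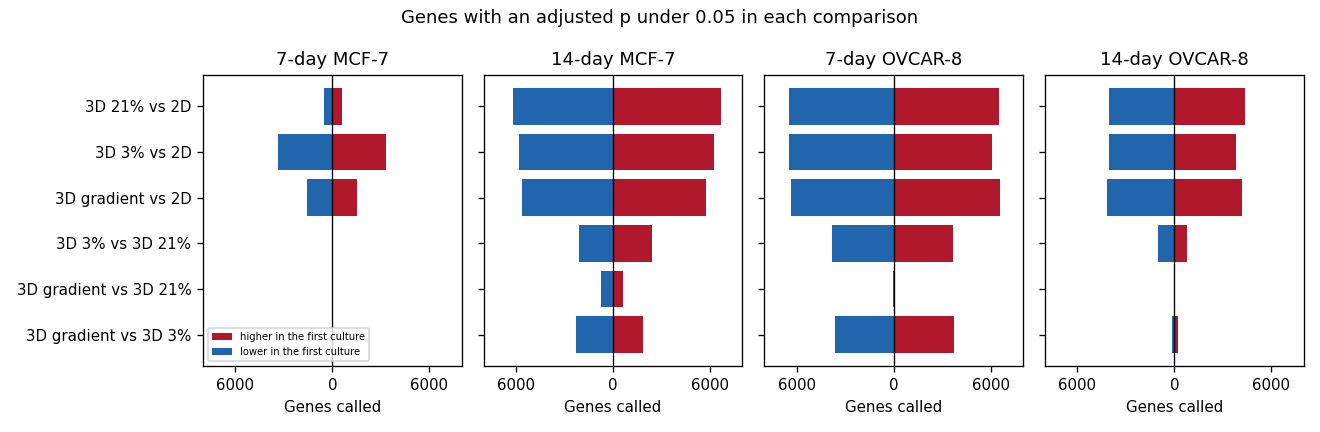
Number of genes with an adjusted p under 0.05 (horizontal axis) in each of the 6 comparisons of a table, with genes higher in the culture named first to the right and lower to the left. In 14-day MCF-7, 12846 genes differed between 3D at 21% oxygen and 2D, and 1388 between gradient and 21% oxygen.

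The first comparison asks what growth in Matrigel changes when the oxygen supplied stays at 21%. In 14-day MCF-7 (n = 4 and 4), low-oxygen genes rose and cell division genes fell. NDRG1 rose by 5.55 (SE 0.08, adjusted p = 1.49e-20), from 13.6 ± 0.854 to 638 ± 49.7 CPM. CA9, at 3 counts over all 2D libraries, was 2060-fold higher (95% counting interval 705 to 10000). CP, the copper carrier ceruloplasmin, rose by 9.66 (SE 0.51, adjusted p = 2.69e-08), and CEACAM5, an adhesion glycoprotein, by 6.5 (SE 0.4). PLEKHS1 fell by 3.5 (SE 0.15, adjusted p = 4.89e-14), IL1R1, the interleukin 1 receptor, by 3.21 (SE 0.11), and BCAT1, a branched-chain aminotransferase, by 3.11 (SE 0.14). SLC2A1 rose by 2.5 (SE 0.08), VEGFA by 1.99 (SE 0.06) and HMGCS1 by 0.19 (SE 0.06), while MKI67 fell by 1.3 (SE 0.1), from 415 ± 54.5 to 168 ± 16.1 CPM. Of 35 HIF targets 31 rose and 3 fell (camera adjusted p = 2.13e-14, 0.0654 with estimated correlation), among them PFKFB4 at 3.98 (SE 0.06), FUT11 at 3.93 (SE 0.06) and the collagen cross-linking enzyme LOXL2 at 4.33 (SE 0.08). Of 23 glycolysis genes 21 rose (camera 1.6e-10, 0.0654 with estimated correlation), ALDOC by 3.93 and ENO2 by 3.94. The 34 tested mitosis genes all fell (camera 6.64e-17, 0.195 with estimated correlation), the mitotic kinases AURKA by 1.93 and PLK1 by 1.78. So did the 37 DNA replication genes (camera 1.34e-13, 0.195 with estimated correlation), with MCM10 at -1.44.

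Genes of matrix and mesenchyme rose in the same 14-day MCF-7 comparison. Of 21 extracellular matrix genes 15 rose and 4 fell (16 and 5 adjusted over the list alone; camera adjusted p = 0.0011, 0.262 with estimated correlation), with TGFBI at 3.57 (SE 0.07), the metalloproteinase inhibitor TIMP3 at 3.03 (SE 0.06) and the laminin chain LAMC2 at 3.02 (SE 0.08). Of 12 mesenchymal genes 11 rose (camera 0.00199, 0.0654 with estimated correlation), among them the fibronectin receptor chain ITGA5 at 3.4 (SE 0.08). OVCAR-8 line markers, TIMP3 among them, rose with these lists in 7 of 8 and fell in 1 (camera 0.0213, 0.41 with estimated correlation), from a sum of 197 to 1020 CPM. Immediate early genes rose in 15 of 21 and fell in 3 (camera 0.00185, 0.449 with estimated correlation), with FOS at 2.43 (SE 0.06). ATF4 targets fell in 21 of 26 and rose in 3 (camera 8.41e-05, 0.195 with estimated correlation), including the aminoacyl-tRNA synthetase GARS at -1.21 (SE 0.04). Oxidative phosphorylation genes fell in 35 of 45 and rose in 3 (camera 2.01e-05, 0.59 with estimated correlation), while COX6C rose by 1.73 (SE 0.07). In all, 6661 genes rose and 6185 fell of 16653 tested.

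In 14-day OVCAR-8 (n = 4 and 4), the same comparison raised low-oxygen, glycolytic and inflammatory genes. NDRG1 rose by 6.05 (SE 0.15, adjusted p = 6.83e-15), from 28.8 ± 0.755 to 1920 ± 348 CPM, and CA9, with 0 counts in 2D, was at least 190-fold higher, at 3.83 ± 0.576 CPM. PI3, an elastase inhibitor with 1 count in 2D, was 3110-fold higher (95% counting interval 558 to 123000). SLPI, another secreted protease inhibitor, rose by 7.68 (SE 0.34, adjusted p = 2.29e-11) and the complement protein C3 by 7.63 (SE 0.47). The growth factor response genes EGR1, FOS and FOSB fell by 5.87 (SE 0.22, adjusted p = 2.1e-12), 5.84 (SE 0.22) and 5.36 (SE 0.22). SLC2A1 rose by 2.68 (SE 0.12) and VEGFA by 2.31 (SE 0.13), and MKI67 fell by 2.48 (SE 0.12), from 305 ± 28.2 to 54.5 ± 5.77 CPM. HIF targets rose in 31 of 35 and fell in 1 (camera adjusted p = 5.2e-27, 0.00285 with estimated correlation), with BNIP3 at 3.39 (SE 0.1). Glycolysis genes rose in 20 of 23 (camera 2.47e-16, 0.0281 with estimated correlation), with the hexokinase HK2 at 2.94. The 34 mitosis genes all fell (camera 1.7e-31, 0.0835 with estimated correlation), KIF2C by 2.55. NF-kB and cytokine genes rose in 21 of 23 (camera 2.37e-09, 0.241 with estimated correlation), with the NF-kB inhibitors NFKBIA at 1.96 (SE 0.11) and TNFAIP3 at 2.71 (SE 0.18).

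Cytoskeletal, stress and ribosomal genes also moved in 14-day OVCAR-8. YAP and SRF targets fell in 22 of 24 and rose in 1 (camera adjusted p = 2.65e-12, 0.0806 with estimated correlation), CTGF by 3.45 (SE 0.15). ATF4 targets fell in 23 of 26 (camera 6.72e-12, 0.0877 with estimated correlation), ATF3 by 2.41 (SE 0.16). Immediate early genes fell in 15 of 21 and rose in 1 (camera 1.5e-07, 0.0994 with estimated correlation), the phosphatase DUSP1 by 3.02 (SE 0.11). DNA replication genes fell in 28 of 37 (30 adjusted over the list alone; camera 1.28e-11, 0.0994 with estimated correlation), the thymidine kinase TK1 by 2.02 (SE 0.18). Cholesterol synthesis genes fell in 17 of 24 (18 adjusted over the list alone; camera 1.4e-06, 0.241 with estimated correlation), the squalene synthase FDFT1 by 1.37 (SE 0.17). Metallothioneins, which bind zinc and copper, rose in 5 of 5 (camera 2.84e-05, 0.0835 with estimated correlation), MT1X by 2.9 (SE 0.17). Ribosomal proteins rose in 47 of 52 (50 adjusted over the list alone; camera 1.9e-15, 0.241 with estimated correlation), RPL28 by 0.98 (SE 0.09). Mitochondrially encoded genes rose in 9 of 13 and fell in 1 (camera 0.00253, 0.555 with estimated correlation), and fibroblast markers fell in 3 of 3 (camera 0.0672). Of 17121 genes tested 4367 rose and 4062 fell. HMGCS1 fell by 0.59 (adjusted p = 0.0275), a call lost without a filter (adjusted p = 0.0959), without 2D replicate 2 (0.0537) or without 2D replicate 3 (0.0613), with a range of 0.00441 to 0.0959 over the alternatives.

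In 7-day OVCAR-8 (n = 4 and 4), DDIT4, a stress-induced inhibitor of mTOR signalling, rose by 4.36 (SE 0.12, adjusted p = 5.15e-16), from 11.2 ± 0.906 to 230 ± 27.2 CPM. ZP1 rose by 4.14 (SE 0.22), NDRG1 by 4.1 (SE 0.19), VEGFA by 3.44 (SE 0.07), HMGCS1 by 1.83 (SE 0.07) and SLC2A1 by 1.4 (SE 0.12). CA9, with 2 counts in 2D, was 136-fold higher (95% counting interval 37.4 to 1130). EGR1 fell by 4.62 (SE 0.21, adjusted p = 1.5e-10), TAGLN, an actin-binding protein, by 3.82 (SE 0.07) and FOS by 3.69 (SE 0.16). MKI67 was 307 ± 24.6 CPM in 3D and 305 ± 20.8 CPM in 2D (adjusted p = 0.961). Of 35 HIF targets 33 rose (camera adjusted p = 1.25e-12, 0.314 with estimated correlation), with PDK1 at 2.6 (SE 0.09). Glycolysis genes rose in 16 of 23 and fell in 5 (camera 0.00314, 0.49 with estimated correlation). The 37 DNA replication genes all fell (camera 9.26e-17, 0.314 with estimated correlation), with PCNA, the polymerase clamp, at -2.1 (SE 0.07). Mitosis genes fell in 26 of 34 and rose in 2 (camera 0.000154, 0.519 with estimated correlation), CDK1 by 1.08.

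The 7-day OVCAR-8 cultures in 3D also raised sterol, amino acid stress and inflammatory genes. Cholesterol synthesis genes rose in 18 of 24 and fell in 3 (camera adjusted p = 2.93e-05, 0.314 with estimated correlation), with PCSK9 at 2.93 (SE 0.09). ATF4 targets rose in 17 of 25 and fell in 6 (camera 0.0206, 0.49 with estimated correlation), the cystine transporter SLC7A11 by 3.0 (SE 0.11) and the asparagine synthetase ASNS by 2.34 (SE 0.09). NF-kB and cytokine genes rose in 20 of 22 (camera 5.43e-06, 0.319 with estimated correlation), with ICAM1 at 2.0 (SE 0.07). Markers of other cell types moved with them, fibroblast markers rising in 3 of 3 (camera 0.0637), from a sum of 23.3 to 49.1 CPM, and immune cell markers in 1 of 2, from a sum of 1.62 to 2.29 CPM. Oxidative phosphorylation genes fell in 42 of 45 and rose in 1 (camera 2.14e-11, 0.314 with estimated correlation), ATP5G1 by 1.52 (SE 0.06), while the 13 mitochondrially encoded genes all rose (camera 0.000512, 0.49 with estimated correlation), MT-CO1 by 2.05 (SE 0.26). Mitochondrial transcripts took 1.559% to 2.801% of the counts in the 2D libraries and 8.147% to 10.17% in the 3D libraries at 21%. Ribosomal proteins fell in 48 of 52 (camera 9.56e-08, 0.49 with estimated correlation). Of 16638 genes tested 6521 rose and 6507 fell.

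In 7-day MCF-7 (n = 3 in 3D at 21% oxygen, n = 4 in 2D), fewer genes passed the test, and replicates lay further apart. PPFIA4, a HIF-induced liprin, rose by 4.12 (SE 0.67, adjusted p = 0.00306), from 6.42 ± 1.64 to 111 ± 101 CPM. The aldolase ALDOC rose by 3.29 (SE 0.61) and UNC13A, a synaptic vesicle priming protein, by 2.86 (SE 0.38). The laminin chain LAMB1 fell by 3.56 (SE 0.58, adjusted p = 0.00312) and TFPI, an inhibitor of coagulation, by 2.5 (SE 0.29). CAV1, the caveolar coat protein, fell by 6.15 (adjusted p = 0.0361), and among the 2D libraries it stood at 62.3 CPM in replicate 4 against a mean of 0.814 CPM in the others. Of 35 HIF targets 17 rose and 1 fell (21 and 2 adjusted over the list alone; camera adjusted p = 1.41e-06, 0.582 with estimated correlation), TMEM45A by 3.58 (SE 0.32) and FUT11 by 2.64 (SE 0.44). The mean log2 CPM of that list was 5.98 and 5.31 in 3D replicates 1 and 3 but 3.76 in replicate 4, where the 2D libraries had 3.65 to 4.1. Cholesterol synthesis genes rose in 6 of 24 (9 adjusted over the list alone; camera 6.17e-07, 0.582 with estimated correlation), STARD4 by 1.96 (SE 0.22). YAP and SRF targets fell in 6 of 22 (14 adjusted over the list alone; camera 1.24e-07, 0.137 with estimated correlation), AMOTL2 by 1.92 (SE 0.18). Ribosomal proteins fell in 14 of 52 (17 adjusted over the list alone; camera 4.23e-15, 0.439 with estimated correlation). None of the 34 mitosis genes passed the edgeR test (camera adjusted p = 0.26), with a list mean of 5.51 in 2D replicate 4, 6.51 to 6.76 in the other 2D libraries and 6.4 to 6.63 in 3D at 21%.

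The other followed genes in that 7-day MCF-7 comparison gave calls that depended on single libraries. NDRG1 rose by 2.93 (adjusted p = 0.0126, range over the alternatives 2.23e-05 to 0.0827), losing the call without a filter (0.0609) or without 3D 21% replicate 1 (0.0827). CA9 rose by 6.49 (adjusted p = 0.03, range 0.000464 to 0.243), losing the call without a filter (0.118), without 2D replicate 1 (0.0626), 2 (0.0769) or 3 (0.0831), and without 3D 21% replicate 1 (0.243) or 3 (0.0519). CAV1 (range 0.0116 to 0.138) lost its call in 5 alternatives, among them without a filter (0.135) and without 3D 21% replicate 1 (0.109), 3 (0.138) or 4 (0.0938). VEGFA was at 86.4 ± 37.9 CPM against 67.1 ± 44 CPM (adjusted p = 0.559, range 0.000424 to 0.984) and was called higher without 2D replicate 4 (0.021) or without the libraries numbered 4 (0.000424). For SLC2A1 (adjusted p = 0.0845, range 0.00511 to 0.309) this held in 3 alternatives, among them without 3D 21% replicate 4 (0.0483) and without the libraries numbered 4 (0.00511). For HMGCS1 (adjusted p = 0.0512, range 0.0131 to 0.171) it held with DESeq2 (0.0152), without 2D replicate 4 (0.0352) and without the libraries numbered 4 (0.0131). MKI67 was at 422 ± 40.9 CPM against 405 ± 159 CPM (adjusted p = 0.919). Of 16142 genes 620 rose and 544 fell, 1164 in all. That count was 551, 548 and 4545 without 2D replicates 2, 3 and 4, 392 and 298 without 3D 21% replicates 1 and 3, 2140 with DESeq2 and 4986 without the libraries numbered 4.

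**Figure D2:**
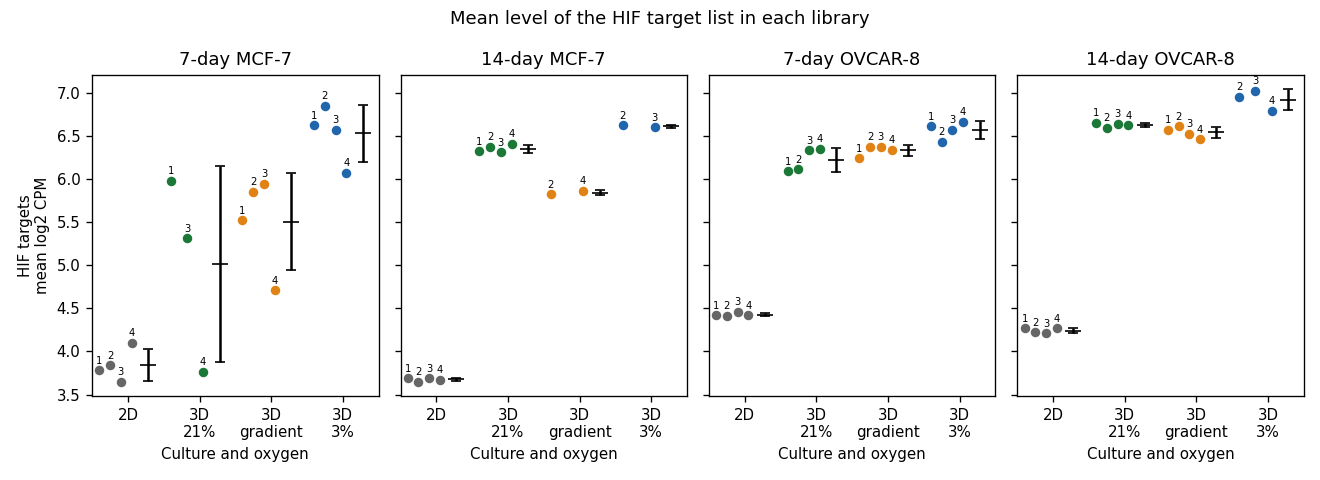
Mean log2 CPM of the 35 HIF targets in each library (points, numbered by replicate), by culture, with the mean and SD of each group beside them. In 7-day MCF-7 the libraries numbered 4 stand at 3.76 at 21% oxygen, 4.71 in the gradient and 6.07 at 3% oxygen, below the other libraries of their group.

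The next comparison asks what lowering the oxygen supplied from 21% to 3% changes in 3D. In 7-day OVCAR-8 (n = 4 and 4), KISS1, a metastasis suppressor peptide, rose by 1.83 (SE 0.1, adjusted p = 2.16e-12), from 13.2 to 46.6 CPM. CA9 rose by 1.69 (SE 0.17), from 3.34 ± 0.722 to 10.6 ± 2.52 CPM, and the complement inhibitor CD55 by 1.65 (SE 0.07). Fibronectin, FN1, fell by 2.56 (SE 0.24, adjusted p = 2.75e-06), from 1080 ± 398 to 183 ± 42.3 CPM, the transcription factor RUNX2 by 2.48 (SE 0.22) and TGFBI by 2.45 (SE 0.27). NDRG1 rose by 1.05 (adjusted p = 0.000202), and VEGFA differed by 0.01 (adjusted p = 0.949). Genes of protein folding in the endoplasmic reticulum rose in 18 of 20 (camera adjusted p = 1.75e-11, 0.0548 with estimated correlation), the chaperones HSPA5 by 0.62 (SE 0.06) and HSP90B1 by 0.75 (SE 0.06). ATF4 targets rose in 17 of 25 (18 adjusted over the list alone; camera 7.59e-08, 0.194 with estimated correlation). Mitosis genes rose in 32 of 34 (33 adjusted over the list alone; camera 8.74e-13, 0.307 with estimated correlation), AURKA by 0.53 (SE 0.06), and DNA replication genes in 24 of 37 (25 adjusted over the list alone; camera 1.44e-06, 0.459 with estimated correlation). HIF targets rose in 22 of 35 and fell in 2 (camera 1.45e-06, 0.44 with estimated correlation), ERO1L by 0.85 (SE 0.07). Interferon-stimulated genes fell in 18 of 24 and rose in 1 (camera 1.44e-06, 0.0399 with estimated correlation), IFI44L by 2.54 (SE 0.18). Extracellular matrix genes fell in 19 of 27 and rose in 5 (camera 4.71e-07, 0.246 with estimated correlation), the collagen COL1A1 by 0.88 (SE 0.06). Markers of other cell types fell with them, the fibroblast markers in 3 of 3 (camera 0.00551, 0.0777 with estimated correlation), from a sum of 49.1 to 25.9 CPM, and the immune cell markers in 2 of 2, from a sum of 2.29 to 1.45 CPM. LUM is in both the fibroblast and the matrix list. Of 16638 genes 3669 rose and 3834 fell.

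Panel genes of proliferation and glucose uptake were less stable in that 7-day OVCAR-8 comparison. MKI67 rose by 0.35 (adjusted p = 0.0235, range over the alternatives 0.0122 to 0.0899), a call lost without a filter (0.0569), without 3D 21% replicate 1 (0.0582) or 3 (0.0703), or without 3D 3% replicate 2 (0.0899). SLC2A1 differed by 0.24 (adjusted p = 0.109, range 0.00433 to 0.273) and was called in 4 alternatives, among them with DESeq2 (0.0484), without 3D 21% replicate 4 (0.00433) or without 3D 3% replicate 2 (0.0271). HMGCS1 differed by 0.0 (adjusted p = 0.984).

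In 14-day OVCAR-8 (n = 3 at 3%, n = 4 at 21%), inflammatory genes were lower at 3% oxygen. PI3 fell by 4.84 (SE 0.75, adjusted p = 0.00112), and the neutrophil-attracting chemokines CXCL2 and CXCL1 by 3.79 (SE 0.55, adjusted p = 0.000699) and 3.54 (SE 0.57). CXCL2 stood at 29.6 ± 18 CPM at 21% and 2.14 ± 0.364 CPM at 3%. The 23 tested NF-kB and cytokine genes all fell (camera adjusted p = 3.55e-21, 0.0886 with estimated correlation), among them NFKBIA by 1.07 (SE 0.12), SOD2 by 1.74 (SE 0.2) and IL1B by 2.42 (SE 0.32). Immune cell markers summed to 2.45 ± 0.847 CPM at 21% and 3.34 ± 0.726 CPM at 3%. CPA4, a carboxypeptidase, rose by 1.67 (SE 0.27, adjusted p = 0.00165), TAGLN by 1.54 (SE 0.12, adjusted p = 1.01e-06) and EMP1, a membrane protein of epithelia, by 1.43 (SE 0.09). HIF targets rose in 13 of 35 and fell in 1 (15 and 1 adjusted over the list alone; camera 3.38e-09, 0.0658 with estimated correlation), with STC2 at 1.27 (SE 0.13), and CA9 rose by 0.92 (adjusted p = 0.00729). YAP and SRF targets rose in 10 of 24 and fell in 1 (11 and 2 adjusted over the list alone; camera 1.13e-08, 0.0886 with estimated correlation), with CRIM1 at 0.98 (SE 0.11). Interferon-stimulated genes fell in 10 of 24 (14 adjusted over the list alone, where 1 rose; camera 9.71e-06, 0.0658 with estimated correlation), IFI44 by 1.03 (SE 0.23). Cholesterol synthesis genes fell in 9 of 24 (13 adjusted over the list alone; camera 9.71e-06, 0.281 with estimated correlation), INSIG1 by 0.9 (SE 0.18). The 1807 calls, 785 up and 1022 down of 17121, became 769 and 853 without 3D 3% replicates 3 and 4, 3189, 1023 and 987 without 3D 21% replicates 1, 2 and 3, and 3618 without the libraries numbered 1.

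Of the other followed genes in 14-day OVCAR-8, 2 passed the test between 3% and 21%. NDRG1 rose by 0.53 (adjusted p = 0.0144, range over the alternatives 0.000381 to 0.113), losing the call without 3D 21% replicate 2 (0.0521) or 3D 3% replicate 3 (0.113). HMGCS1 fell by 0.91 (adjusted p = 0.0225, range 4.34e-05 to 0.105), losing it without a filter (0.105) and without 3D 21% replicate 2 (0.0675) or 4 (0.0555) or 3D 3% replicate 3 (0.0663) or 4 (0.086). SLC2A1 differed by 0.28 (adjusted p = 0.135, range 0.0124 to 0.395) and was called in 4 alternatives, among them without the libraries numbered 1 (0.0124), without 3D 21% replicate 1 (0.0216) or 3D 3% replicate 4 (0.0444). MKI67 differed by 0.31 (adjusted p = 0.115, range 0.0376 to 0.395) and was called in 2 alternatives, among them without the libraries numbered 1 (0.0452). VEGFA differed by 0.0 (adjusted p = 0.998).

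In 14-day MCF-7 (n = 2 at 3%, n = 4 at 21%), the gap junction gene GJA1 rose at 3% oxygen by 4.37 (SE 0.39, adjusted p = 4.98e-05), from 2.41 ± 0.945 to 49 ± 26.8 CPM. C1orf95 rose by 3.24 (SE 0.29) and the proteoglycan SPOCK1 by 2.56 (SE 0.1, adjusted p = 1.1e-12). TM4SF1, a tetraspanin-like membrane protein, fell by 2.32 (SE 0.15, adjusted p = 3.7e-08), METTL7A by 1.73 (SE 0.17) and AZGP1 by 1.69 (SE 0.14). CA9 rose by 1.37 (SE 0.09, adjusted p = 4.62e-09), from 33.7 ± 3.01 to 87 ± 6.88 CPM, and SLC2A1 by 0.54 (adjusted p = 0.00033). NDRG1 differed by 0.1 (adjusted p = 0.358) and HMGCS1 by 0.11 (adjusted p = 0.317). HIF targets rose in 18 of 35 and fell in 3 (18 and 4 adjusted over the list alone; camera 4.02e-07, 0.133 with estimated correlation), the oxygen-sensing hydroxylase EGLN3 by 1.48 (SE 0.07). Glycolysis genes rose in 14 of 23 (15 adjusted over the list alone; camera 1.92e-06, 0.133 with estimated correlation), the lactate transporter SLC16A1 by 1.14 (SE 0.07). Mitosis genes fell in 21 of 34 and rose in 1 (26 and 1 adjusted over the list alone; camera 3.19e-08, 0.349 with estimated correlation), AURKA by 0.44 (SE 0.06). Interferon-stimulated genes fell in 17 of 25 and rose in 1 (19 and 1 adjusted over the list alone; camera 1.41e-06, 0.133 with estimated correlation), the antiviral sensor genes IFIH1 by 0.71 (SE 0.1) and OAS2 by 2.09 (SE 0.36). Epithelial adhesion genes rose in 9 of 22 and fell in 2 (11 and 2 adjusted over the list alone; camera 0.000113, 0.133 with estimated correlation), JUP by 0.53 (SE 0.06). MKI67 rose by 0.37 (adjusted p = 0.0297, range over the alternatives 5.44e-06 to 0.282), losing the call without 3D 21% replicate 1 (0.0611), 2 (0.077) or 3 (0.0597) or 3D 3% replicate 3 (0.282). VEGFA differed by 0.15 (adjusted p = 0.127, range 0.0259 to 0.405) and was called in 2 alternatives, among them without 3D 21% replicate 1 (0.0259). The 4550 calls, 2433 up and 2117 down of 16653, became 2696 and 2159 without 3D 3% replicates 2 and 3.

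In 7-day MCF-7 (n = 4 at 3%, n = 3 at 21%), 23 genes rose and 16 fell of 16142. BMPER, a regulator of bone morphogenetic protein signalling, rose by 2.31 (SE 0.29, adjusted p = 0.0168), from 2.74 ± 0.614 to 13.7 ± 5.06 CPM, TMEM45A by 1.83 (SE 0.29, adjusted p = 0.0216) and SLC16A1 by 1.76 (SE 0.27, adjusted p = 0.0212). TAF9B fell by 2.51 (SE 0.41, adjusted p = 0.0216), the glutathione transferase GSTM3 by 0.84 (SE 0.15, adjusted p = 0.039) and the small GTPase RHOD by 0.83 (SE 0.16, adjusted p = 0.0444). HIF targets rose in 1 of 35 (28 adjusted over the list alone; camera adjusted p = 8.43e-20, 0.447 with estimated correlation), and glycolysis genes in 1 of 23 (16 adjusted over the list alone; camera 5.25e-13, 0.447 with estimated correlation). No mitosis or DNA replication gene passed the edgeR test (camera 1.29e-05 and 6.41e-11, both downward, and adjusted p = 0.537 and 0.5 with estimated correlation). The mitosis list mean was 5.68 in 3D 3% replicate 2 and 6.26 to 6.36 in the other 3% libraries. Mitochondrially encoded genes were lower by camera too (0 called, 10 adjusted over the list alone; camera 3.42e-07, 0.447 with estimated correlation). BMPER (range over the alternatives 2.36e-11 to 0.142), TMEM45A (2.94e-07 to 0.169) and SLC16A1 (8.21e-08 to 0.169) each lost the call without 3D 21% replicate 3 (0.142, 0.169 and 0.169) or 4 (0.064, 0.0997 and 0.133) and without 3D 3% replicate 2 (0.0572, 0.0634 and 0.0634) or 3 (0.0655, 0.077 and 0.077). TAF9B (8.49e-07 to 0.169), GSTM3 (0.000186 to 0.241) and RHOD (0.00048 to 0.262) lost it without any of those libraries (0.0844 to 0.262) and also without 3D 3% replicate 1 (0.0732, 0.0849 and 0.0863), TAF9B without a filter too (0.0598). The 39 calls became 198 with the block (127 up, 71 down), 720 with DESeq2, 1182 without the libraries numbered 4, 14 and 335 without 3D 3% replicates 1 and 4, 221 without 3D 21% replicate 1, and 0 without 3D 3% replicate 2 or 3 or 3D 21% replicate 3 or 4. CA9 at 3.22 (adjusted p = 0.147), NDRG1 at 1.72 (0.184), VEGFA at 1.58 (0.0773), SLC2A1 at 0.9 (0.0528), HMGCS1 at 0.68 (0.283) and MKI67 at -0.35 (0.52) were not called. Without the libraries numbered 4 the first 5 were (0.033, 0.0185, 0.00278, 0.00864 and 0.0427, in ranges of 0.033 to 0.444, 0.0185 to 0.469, 0.00255 to 0.323, 0.000448 to 0.262 and 0.0427 to 0.618). So were CA9, VEGFA and SLC2A1 without 3D 21% replicate 1 (0.0403, 0.0458 and 0.0307), VEGFA and SLC2A1 with DESeq2 (0.00255 and 0.000448), and SLC2A1 without a filter (0.025), with the block (0.0296) or without 3D 3% replicate 4 (0.0202).

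**Figure D3:**
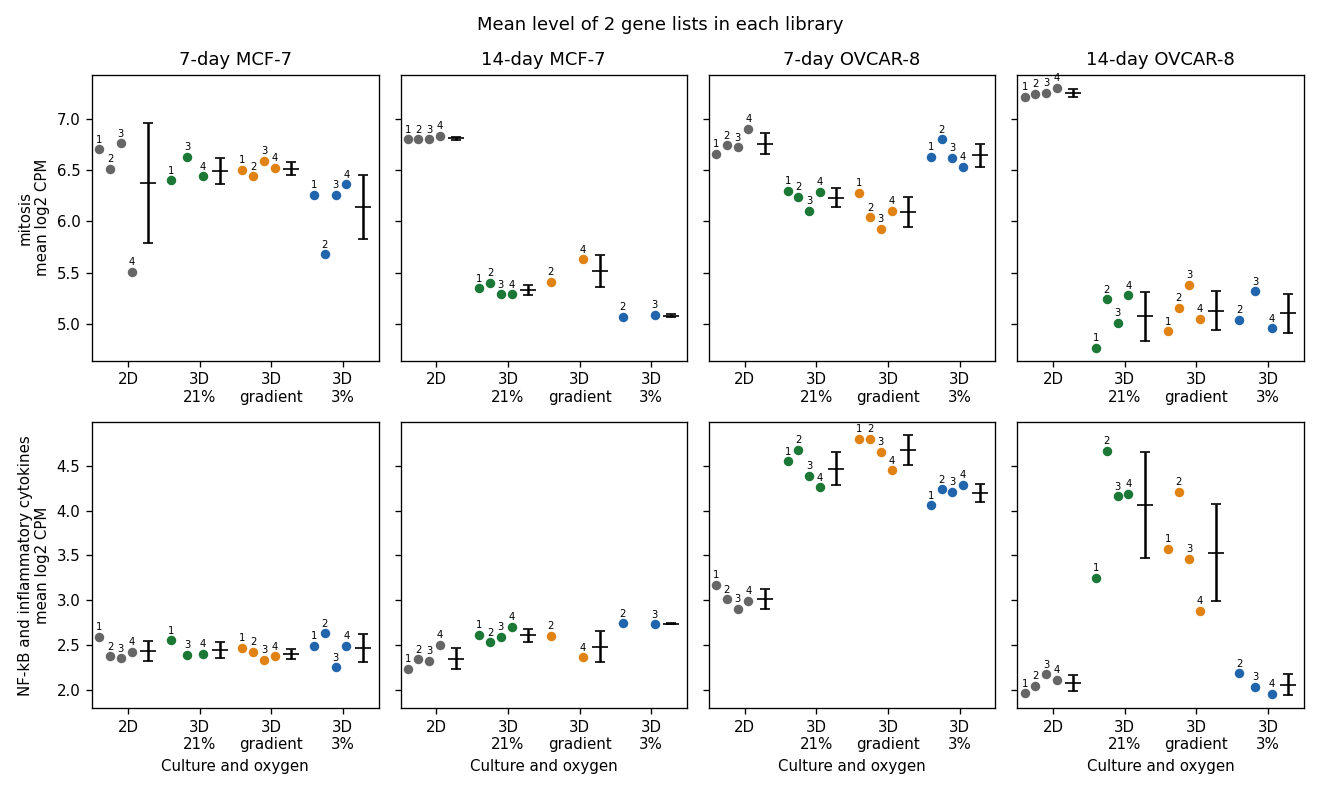
Mean log2 CPM of the mitosis list (upper row) and of the NF-kB and inflammatory cytokine list (lower row) in each library (points, numbered by replicate), with the mean and SD of each group. In 14-day OVCAR-8 all 34 mitosis genes fell between 2D and 3D at 21% oxygen, and all 23 NF-kB and cytokine genes between 21% and 3% oxygen.

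The gradient was then compared with uniform 21% oxygen, the question nearest to the purpose of the bioreactor. In 14-day MCF-7 (n = 2 in the gradient, n = 4 at 21%), low-oxygen genes were lower in the gradient and DNA replication genes higher. ADM, the vasodilator adrenomedullin, fell by 2.94 (SE 0.13, adjusted p = 8.63e-11), from 40.1 ± 5.61 to 5.24 ± 0.369 CPM, ANKRD37 by 1.85 (SE 0.13) and IGFBP3, which binds insulin-like growth factors, by 1.84 (SE 0.16). ARL4A rose by 0.72 (SE 0.1, adjusted p = 0.000104) and PLEKHB1 by 0.71 (SE 0.09). The adenylate cyclase ADCY5 rose by 0.71 (adjusted p = 0.00329, range over the alternatives 6.2e-12 to 0.0586), losing the call without gradient replicate 4 (0.0586). HIF targets fell in 18 of 35 (24 adjusted over the list alone, where 2 rose; camera adjusted p = 2.25e-18, 0.0418 with estimated correlation), DDIT4 by 1.53 (SE 0.08) and ANGPTL4 by 1.38 (SE 0.11). NDRG1 fell by 0.55 (adjusted p = 0.000246), SLC2A1 by 0.58 (0.00129) and VEGFA by 0.44 (0.00076), while CA9 differed by -0.04 (0.834). DNA replication genes rose in 26 of 37 (36 adjusted over the list alone; camera 3.52e-28, 0.105 with estimated correlation), the flap nuclease FEN1 by 0.49 (SE 0.05). Mitosis genes rose in 14 of 34 (20 adjusted over the list alone; camera 6.11e-10, 0.245 with estimated correlation), CDK1 by 0.51 (SE 0.07). Immediate early genes fell in 12 of 21 and rose in 1 (13 and 1 adjusted over the list alone; camera 3.63e-07, 0.19 with estimated correlation), FOS by 1.11 (SE 0.07). Extracellular matrix genes fell in 6 of 21 (8 adjusted over the list alone; camera 2.75e-07, 0.117 with estimated correlation), TIMP3 by 0.63 (SE 0.07). Of 16653 genes 619 rose and 769 fell. These 1388 calls became 859 without 3D 21% replicate 4 and 559 without gradient replicate 4.

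In 7-day OVCAR-8 (n = 4 and 4), 77 genes rose in the gradient and 74 fell of 16638. The cholesterol exporter ABCA1 rose by 0.65 (SE 0.1, adjusted p = 0.000982) and the calcium-binding protein S100A4 by 0.61 (SE 0.11, adjusted p = 0.00406). PPL, a desmosomal plakin, rose by 0.69 (adjusted p = 0.0112, range over the alternatives 1.21e-06 to 0.0891), a call lost without 3D 21% replicate 1 (0.0613) or gradient replicate 3 (0.0891) or 4 (0.0674). POP1, an RNA-processing protein, fell by 0.66 (SE 0.1, adjusted p = 0.000982), SLC7A11 by 0.64 (SE 0.1) and the pseudogene SFTA1P by 0.6 (SE 0.1). ATF4 targets fell in 7 of 25 (13 adjusted over the list alone; camera adjusted p = 5.02e-14, 0.0366 with estimated correlation), ASNS by 0.5 (SE 0.08) and ALDH1L2 by 0.43 (SE 0.07). Mesenchymal genes rose in 2 of 19 (3 adjusted over the list alone; camera 1.08e-07, 0.0189 with estimated correlation). Fibroblast markers summed to 57.7 ± 4.28 CPM in the gradient and 49.1 ± 3.1 CPM at 21%. PDGFRB, in both lists, rose by 0.29 (adjusted p = 0.0467), a call lost with RLE (0.0541) and without any library but gradient replicate 1 (0.0705 to 0.217). Metallothioneins fell in 1 of 5 (2 adjusted over the list alone; camera 0.000105, 0.0189 with estimated correlation), MT1E by 0.41 (SE 0.07). Of 35 HIF targets 4 rose and 2 fell (7 and 4 adjusted over the list alone; camera 0.000105, 0.517 with estimated correlation). Without 3D 21% replicate 1, BNIP3 (0.152), BNIP3L (0.155) and AK4 (0.0896) lost their rising and BHLHE40 (0.059) its falling call. CA9 differed by 0.72 (adjusted p = 0.0511, range 0.000108 to 0.179) and was called with DESeq2 (0.0192), without a filter (0.000108), without 3D 21% replicate 2 (0.0365) or gradient replicate 1 (0.0254). The 151 calls became 76 and 93 without 3D 21% replicates 1 and 2, 245, 94, 61 and 74 without gradient replicates 1 to 4, 348 without a filter and 259 with DESeq2.

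In 14-day OVCAR-8 (n = 4 and 4), 54 genes rose in the gradient and 27 fell of 17121. CPA4 rose by 2.43 (SE 0.26, adjusted p = 0.000246), from 5.13 ± 1.01 to 27.7 ± 12.8 CPM, and SDPR, a caveolar protein, by 1.26 (SE 0.11, adjusted p = 3.22e-05). C10orf10 fell by 1.31 (SE 0.17, adjusted p = 0.00112) and the phosphodiesterase PDE2A by 0.82 (SE 0.1). DDIT4 fell by 1.0 (adjusted p = 0.0108, range over the alternatives 5.12e-06 to 0.0665), losing the call without a filter (0.0561) or without the libraries numbered 1 (0.0665). The integrin chain ITGB4 rose by 1.19 (adjusted p = 0.0354, range 6.22e-05 to 0.144), losing it without a filter (0.144), without the libraries numbered 1 (0.0621), without 3D 21% replicate 2 (0.0817), 3 (0.081) or 4 (0.0993), and without gradient replicate 1 (0.125), 3 (0.0697) or 4 (0.109). HIF targets fell in 1 of 35 (6 adjusted over the list alone, where 2 rose; camera adjusted p = 0.14). No NF-kB gene of 23 passed the edgeR test (4 fell adjusted over the list alone; camera 1.24e-07 downward, 0.496 with estimated correlation). The 81 calls became 151, 52, 47 and 44 without 3D 21% replicates 1 to 4, 30 and 37 without gradient replicates 3 and 4, and 270 with DESeq2. In 7-day MCF-7 (n = 4 and 3), edgeR called 0 of 16142 genes between gradient and 21% oxygen, with 201 at an unadjusted p under 0.05, and DESeq2 also called 0. Camera ranked HIF targets higher in the gradient (4.59e-12, 0.672 with estimated correlation) and interferon-stimulated genes lower (4.75e-06, 0.672 with estimated correlation). The HIF list mean was 5.98, 5.31 and 3.76 in 3D 21% replicates 1, 3 and 4 and 4.71 to 5.94 in the gradient, and the interferon list mean 2.07, 2.21 and 3.42 against 1.94 to 2.63, so 3D 21% replicate 4 stood apart in both. Both lists went the other way between libraries numbered 1 (5.98 to 5.52, 2.07 to 2.14). They did not for 3 (5.31 to 5.94, 2.21 to 1.94) or 4.

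Between the gradient and uniform 3% oxygen in 3D, HIF targets were lower in the gradient in 3 tables by single genes. In 14-day MCF-7 (n = 2 and 2) they fell in 31 of 35 (31 adjusted over the list alone, where 1 rose; camera adjusted p = 3e-27, 0.0113 with estimated correlation), ADM by 2.95 (SE 0.14) and CA9 by 1.41 (SE 0.11, adjusted p = 6.2e-08). There GJA1 fell by 3.46 (SE 0.47) and DMP1 and METTL7A rose by 3.45 (SE 0.2) and 1.73 (SE 0.19). Mitosis genes rose in 31 of 34 (camera 8.36e-18, 0.114 with estimated correlation), CDK1 by 0.81 (SE 0.09), and interferon-stimulated genes in 14 of 25 (20 adjusted over the list alone; camera 2.96e-08, 0.0496 with estimated correlation). Of 16653 genes 1821 rose and 2310 fell, and the 4131 calls became 2655 and 1981 without 3D 3% replicates 2 and 3 and 1999 without gradient replicate 4. In 7-day OVCAR-8 (n = 4 and 4) FN1 rose by 2.76 (SE 0.25, adjusted p = 1.43e-06) and TGFBI by 2.65 (SE 0.27), and KISS1 and DAW1 fell by 1.64 (SE 0.1) and 1.29 (SE 0.1). HIF targets fell there in 15 of 35 and rose in 1 (camera 0.000239, 0.547 with estimated correlation). The 34 mitosis genes all fell (camera 1.56e-18, 0.161 with estimated correlation), AURKA by 0.7 (SE 0.06). Unfolded protein response genes fell in 19 of 20 (camera 3.72e-13, 0.0331 with estimated correlation), HSPA5 by 0.71 (SE 0.06), and interferon-stimulated genes rose in 18 of 24 (camera 2.73e-08, 0.0144 with estimated correlation), IFI44L by 3.1 (SE 0.17). Of 16638 genes 3713 rose and 3646 fell.

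In 14-day OVCAR-8 (n = 4 in the gradient, n = 3 at 3%), the chemokines CXCL2 and CXCL1 were higher in the gradient by 3.2 (adjusted p = 0.00694, range over the alternatives 5.69e-07 to 0.0529) and 2.88 (adjusted p = 0.0156, range 6.04e-05 to 0.0888). Both lost the call without 3D 3% replicate 3 (0.0529 and 0.0888), and CXCL1 also without a filter (0.0761) or without 3D 3% replicate 4 (0.0568). NF-kB and cytokine genes rose in 11 of 23 (22 adjusted over the list alone; camera adjusted p = 3.62e-20, 0.0936 with estimated correlation), IL1B by 2.04 (SE 0.31, adjusted p = 0.00335). DDIT4 fell by 1.12 (SE 0.18, adjusted p = 0.00376), ADM by 1.0 (SE 0.13) and NDRG1 by 0.85 (SE 0.13). AHNAK2 fell by 1.02 (adjusted p = 0.0191, range 0.000157 to 0.077), losing the call without a filter (0.077), without 3D 3% replicate 2 (0.0701) or 3 (0.0705) or gradient replicate 2 (0.0633). HIF targets fell in 9 of 35 (24 adjusted over the list alone; camera 2.62e-21, 0.0037 with estimated correlation), and interferon-stimulated genes rose in 8 of 24 (16 adjusted over the list alone; camera 6.4e-15, 0.00186 with estimated correlation), IFI44L by 1.6 (SE 0.22). The 344 calls, 218 up and 126 down of 17121, became 113, 93 and 118 without 3D 3% replicates 2 to 4, 129 and 160 without gradient replicates 2 and 4, 712 with DESeq2 and 1117 without the libraries numbered 1. In 7-day MCF-7 (n = 4 and 4), 1 gene of 16142 was called by edgeR. BMPER fell by 2.29 (SE 0.26, adjusted p = 0.00516, range 2.33e-13 to 0.0566), from 13.7 ± 5.06 to 2.8 ± 0.693 CPM, a call lost without gradient replicate 2 (0.0566). That count was 38 with the block (4 up, 34 down), 3 and 12 without 3D 3% replicates 1 and 4, 0 without gradient replicate 2, 9 without a filter, 211 with DESeq2 and 683 without the libraries numbered 4. HIF targets were lower by camera (0 called, 18 adjusted over the list alone; camera 4.01e-15, 0.411 with estimated correlation).

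The comparisons of 3D at 3% oxygen and in the gradient with 2D ask what gel and oxygen change together. At 3%, HIF targets rose in 32, 32, 33 and 32 of 35 in 7-day MCF-7 (n = 4 and 4), 14-day MCF-7 (n = 2 and 4), 7-day OVCAR-8 (n = 4 and 4) and 14-day OVCAR-8 (n = 3 and 4), by camera at 5.94e-13, 7.63e-17, 5.1e-16 and 1.78e-31, with adjusted p = 0.573, 0.046, 0.215 and 0.00137 with estimated correlation. Those falling were 1, 2, 1 and 1, and adjusted over the list alone 34 rose in 7-day OVCAR-8 and 33 in 14-day OVCAR-8. In 7-day MCF-7 at 3%, CA9 rose by 9.71 (SE 1.51, adjusted p = 0.000301), CASP14, a caspase of skin differentiation, by 7.06 (SE 1.04), NDRG1 by 4.65 (SE 0.64) and VEGFA by 1.95 (SE 0.36), while LAMB1 fell by 3.62 (SE 0.52) and EFEMP1, a fibulin of the matrix, by 3.14 (SE 0.33). At 3% against 2D in 14-day MCF-7, CA9 was 5350-fold higher (95% counting interval 1830 to 26000) and GJA1 4530-fold (1250 to 37400), and IL1R1 and BCAT1 fell by 4.12 (SE 0.16) and 4.09 (SE 0.22). In 7-day OVCAR-8 CA9 was 444-fold higher (123 to 3680), NDRG1 rose by 5.15 (SE 0.2), and TGFBI and NNMT fell by 4.83 (SE 0.27) and 4.33 (SE 0.15). In 14-day OVCAR-8 the calcium-regulating hormone STC1 rose by 7.4 (SE 0.22) and NDRG1 by 6.58 (SE 0.16), CA9 was at least 360-fold higher, and EGR1 and FOS fell by 6.32 and 5.72. Of the genes tested 3298, 6234, 6105 and 3790 rose and 3389, 5840, 6454 and 4056 fell, in the same order of tables.

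In the gradient against 2D, HIF targets rose in 23, 30, 33 and 30 of 35 in the same order of tables (n = 4 and 4, 2 and 4, 4 and 4, 4 and 4), by camera at 3.09e-10, 8.3e-15, 8.79e-13 and 2.86e-25, with adjusted p = 0.453, 0.0546, 0.23 and 0.00377 with estimated correlation. Those falling were 2, 3, 1 and 2, and adjusted over the list alone 26 rose in 7-day MCF-7. In 7-day MCF-7 CASP14 rose by 4.79 (SE 0.96, adjusted p = 0.00467) and PPFIA4 by 4.43 (SE 0.66). CAV1 fell by 5.71 (adjusted p = 0.0125, range over the alternatives 0.00741 to 0.0625) and OLFML3 by 3.54 (adjusted p = 0.0129, range 0.00683 to 0.0589), both losing the call in 2 alternatives, among them without a filter (0.0565 and 0.0569). In 14-day MCF-7 CA9 was 2010-fold higher (95% counting interval 687 to 9760), CP rose by 9.3 (SE 0.57), and IL1R1 and NECAB1 fell by 3.95 (SE 0.16) and 3.6 (SE 0.14). In 7-day OVCAR-8 CA9 was 227-fold higher (62.4 to 1880), NDRG1 rose by 4.41 (SE 0.2) and DDIT4 by 4.02 (SE 0.12), and EGR1 and FOS fell by 4.42 and 3.65. In 14-day OVCAR-8 STC1 rose by 7.05 (SE 0.22) and SLPI by 6.97 (SE 0.34), CA9 was at least 244-fold higher, and EGR1 and FOSB fell by 5.05 and 4.71. Mitosis genes fell in 34 of 34 in both 14-day lines (camera 1.21e-17 in MCF-7 and 6.53e-31 in OVCAR-8, and adjusted p = 0.182 and 0.0925 with estimated correlation). Of the genes tested 1541, 5732, 6563 and 4171 rose and 1587, 5655, 6378 and 4156 fell. The 3128 calls in 7-day MCF-7 became 2034, 1910 and 6155 without 2D replicates 2, 3 and 4, 1591 and 1892 without gradient replicates 2 and 3, and 6993 without the libraries numbered 4.

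Calls shared between tables were counted next, to ask which genes moved alike. Between 3D at 21% oxygen and 2D at day 14, 2357 genes rose and 2509 fell in both lines, where independent lists would share 1372 and 1449, and 1090 moved in opposite directions. HIF-induced NDRG1, FUT11, BNIP3, ALDOC and PFKFB4 rose in both, and FAM83D, KIF2C, CDC20, AURKA and TPX2, genes of the mitotic spindle, fell in both. At day 7 the lines shared 367 rising and 366 falling genes against 183.8 and 217.6 for independent lists (one-sided Fisher's exact test, p = 2.51e-63 and 4.78e-42), with 113 opposite. They include TMEM45A, STARD4, SPIN3, ENTPD8 and the chemokine receptor CXCR4 upward and AMOTL2, MYO1B, KRT80, TGFB2 and ATP6V0E2 downward. The 2 days of MCF-7 shared 552 and 465 against 238.7 and 208 (exact p = 6e-163 and 1.06e-119), with 31 opposite. PARM1, GCNT1, TMEM45A, SHC4 and EGR3 rose and AMOTL2, KRT80, RHOBTB3, CLEC3A and MYO1B fell on both days. The 2 days of OVCAR-8 shared 2745 and 2649 against 1582 and 1589, with 1262 opposite. The collagen-modifying enzymes P4HA1, P4HA2 and PLOD2, with FUT11 and BNIP3, rose, and DUSP1, CTGF, TUFT1, HBEGF and FOS fell. For 7-day MCF-7 and OVCAR-8, the 733 shared calls became 1400 with DESeq2, 481 without a filter and 3316 without the libraries numbered 4. For the days of MCF-7, 1017 became 1839 with DESeq2 and 4531 without them.

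For 3% against 21% oxygen in 3D, the lines shared 278 rising and 264 falling genes at day 14 against 106.2 and 108.7 for independent lists (one-sided Fisher's exact test, p = 2.12e-59 and 1.26e-47), with 83 opposite. PODXL, STC2, PLOD2, LIMCH1 and AK4 rose, and SLC25A35, NSMCE4A, SAT1, ACSS2 and GFPT2 fell. The days of OVCAR-8 shared 322 and 431 against 175.8 and 234.7 (exact p = 2.3e-33 and 1.56e-45), with 251 opposite. TAGLN, DPYSL2, NIPAL3, STC2 and AK4 rose, and NNMT, C1S, PNPLA3, TNFRSF9 and GBP2 fell. The days of MCF-7 shared 16 and 9 against 3.471 and 2.103 (exact p = 5.86e-09 and 5.5e-05), with 1 opposite, among them BMPER, SLC16A1, PARM1, ZMYND8 and TMEM45A upward and CCDC69, DECR1, ARHGAP18, ACAT1 and C16orf62 downward. At day 7 the lines shared 4 and 5 against 4.55 and 2.674 (exact p = 0.702 and 0.107), with 6 opposite. BMPER, KRT15, PARM1 and TMEM45A rose and TMEM37, CCDC69, GSTM3, ARHGAP18 and CLCN4 fell. The 7-day MCF-7 call of each gene named here for a list with that table was lost without 3D 21% replicate 3 or 4 or without 3D 3% replicate 2 or 3. In 7-day OVCAR-8, PARM1 (adjusted p = 0.0258) lost its call without 3D 21% replicate 1 or 3 or 3D 3% replicate 2 or 3 (0.0521 to 0.0978), and TMEM45A (0.026) without 3D 21% replicate 1 or 2 or 3D 3% replicate 1, 3 or 4 (0.0507 to 0.108). The 9 shared genes became 210 with DESeq2, 14 without a filter and 293 without the libraries numbered 4. The 25 of the MCF-7 days became 323 with DESeq2 and 493 without them. Without the libraries numbered 1 in 14-day OVCAR-8, the 542 of day 14 became 1174 and the 753 of OVCAR-8 became 1151.

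Whether the lines responded differently was tested as the OVCAR-8 change minus the MCF-7 change. For 3D at 21% oxygen against 2D at day 14 (n = 4 in each group), 7885 genes differed. FOS, which rose by 2.43 in MCF-7 and fell by 5.84 in OVCAR-8, had a difference of -8.28 (SE 0.21, edgeR adjusted p = 1.08e-21). SEMA3E, LOXL2, CDC42EP3 and IGFBP3 stood at -4.55, -4.41, -3.39 and -5.64. STC1 had a difference of 6.49 (SE 0.23, adjusted p = 8.02e-19), and ARRDC3, CAV1, NPNT and NT5E of 3.58, 3.61, 2.93 and 3.64. MKI67, lower in 3D in both lines, had a difference of -1.19 (adjusted p = 3.9e-07), while the rise of SLC2A1 differed by 0.17 (adjusted p = 0.382). Ribosomal proteins had a higher change in OVCAR-8 in 46 of 52, and mitosis genes a lower one in 29 of 34 and cholesterol synthesis genes in 17 of 25. At day 7, where the kit also differs (n = 4, and 3 in MCF-7 3D at 21%), 6478 genes differed. FRMD4A, UNC13D, RHBDF1, SIN3B and HID1 stood at 3.83, 2.9, 1.82, 1.5 and 1.99, and TAGLN, PARM1, GCNT1, COX6C and GLUD1 at -4.29, -3.86, -1.64, -1.67 and -1.15. VEGFA rose more in OVCAR-8 by 3.08 (SE 0.4, adjusted p = 1.81e-06). DNA replication genes had a lower change in OVCAR-8 in 32 of 37, and ATF4 targets a higher one in 16 of 26.

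For 3% against 21% oxygen at day 7, 2778 genes differed between the lines. ZNF114, HEXB, GCNT2, NUCB2 and ARNTL2 stood at 1.51, 0.83, 1.68, 1.17 and 1.15, and AMIGO2, ITGB4, VIPR1, RUNX2 and PNPLA3 at -3.37, -2.37, -2.19, -2.98 and -2.44 (edgeR adjusted p = 2.24e-08 for AMIGO2). Mitosis genes had a higher change in OVCAR-8 in 19 of 34 and HIF targets a lower one in 11 of 35. In MCF-7, 3D 3% replicate 2 stood apart on the mitosis list and the libraries numbered 4 on the HIF list. Without MCF-7 3D 3% replicate 2 the count was 1640, without MCF-7 3D 21% replicates 3 and 4 it was 1687 and 1743, without a filter 1768 and without the libraries numbered 4 it was 4692. At day 14 (n = 2 for MCF-7 at 3%), 749 genes differed. EMP1, ANXA6, ATP6V0A4, SERTAD2 and ANKRD37 stood at 1.78, 1.2, 1.88, 1.07 and 1.64, and HLA-B, GJA1, LRRC15, NFKBIZ and PTPRK at -1.41, -4.37, -2.8, -3.59 and -1.19 (adjusted p = 1.78e-08 for HLA-B). NF-kB and cytokine genes had a lower change in OVCAR-8 in 5 of 23. This count was 417 and 246 without MCF-7 3D 3% replicates 2 and 3, 1143 with DESeq2 and 1343 without the libraries numbered 1 in OVCAR-8.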

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

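Of the tests weighed here, those of 3D 21% replicate 4, of exchanged labels, of a batch, of immune cells, of a single library, of the scaling and of a 3% or gradient library in 2D were chosen after the result was seen, and those of mixed cells and of the splits before. The 7-day line difference splits that part the MCF-7 pairs were also added after.

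In 7-day MCF-7, HIF targets were lower in each 3D library numbered 4 than in the other libraries of its culture. Over genes outside the HIF and glycolysis lists, 3D 21% replicate 4 lay at 0.51 between 2D replicates 1 to 3 (0) and the other 3D libraries (1), not near 0 as another library like those 2D replicates would. The library labelled 2D replicate 4 lay at 0.55 on the same scale, so this position argues only against a library like 2D replicates 1 to 3. The 3 libraries numbered 4 deviated from their groups together with a lowest correlation of 0.65, as a batch shared by the number predicts. An exchange of labels between it and 2D replicate 4 gave that other library a lowest correlation of 0.12, against 0.65 for the one labelled 3D 21% replicate 4. Neither this nor the positions decides whether labels were exchanged. No biological explanation was tested, since the labels give nothing else that sets number 4 apart.

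In 14-day OVCAR-8, NF-kB and cytokine genes were lower at 3% than at 21% oxygen in 3D. Immune cells in the 21% cultures would raise their markers there, and their mean sum was lower (-0.89 CPM, SE 0.6). Sums of a few CPM do not decide this, but the labels name only OVCAR-8 cells. All 4 libraries at 21% lay above every library at 3%, so 1 library does not carry the difference, although replicate 1 was nearest to them. A scaling factor moves all genes of a library alike, while the median log2 fold change of the list lay at -1.71 against that of all tested genes (quartiles of the list -3.381 and -1.081, median of all genes -0.031), so the scaling could not account for it. The biological explanation in the design is the oxygen supplied. Of 35 splits 2, the real one among them, gave at least 1807 genes. The other, with 2659, only moved 21% replicate 1 to the 3% arm, so it leaves chance undecided.

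In 7-day MCF-7, 2D replicate 4 stood apart from the other 2D libraries. VEGFA was 133 CPM there (41.9 to 50.2 in the others), MKI67 170 CPM (451 to 507) and HMGCS1 79.8 CPM (183 to 196). It lay at 0.55 on the scale above, and an exchange of labels with 3D 21% replicate 4 stays open. OVCAR-8 cells mixed in at the share that CAV1 needs would raise the other OVCAR-8 markers, and the median ratio of observed to needed rise was 8.8e-05. A 3% or gradient library under this label would have their HIF list mean, and it was 4.1, under every one of them. No biological explanation was tested.

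The other libraries far from their group were these, and chance flags about 1 in 20 groups, against 16 of 215 tests here. In 7-day MCF-7 3D 3%, replicate 1 had 37.03 M counts (others 22.24 to 24.14) and 24127 genes detected (23026 to 23088). There replicate 2 had MKI67 at 209 CPM (359 to 387) and a mitosis list mean of 5.68 (6.26 to 6.36), and replicate 4 an interferon list mean of 3.12 (1.56 to 1.71). In 14-day MCF-7 2D, replicate 3 lay at -4.06 on the second principal component (1.917 to 2.122), replicate 1 had SLC2A1 at 146 CPM (134 to 136), and replicate 4 a mitosis list mean of 6.83 (6.8 in the others). In 7-day OVCAR-8, 2D replicate 4 had MKI67 at 336 CPM (293 to 299) and gradient replicate 1 at 335 CPM (240 to 254). In 7-day OVCAR-8 3D 3%, replicate 2 had 2.668% of counts in its top gene (1.396 to 1.584) and 12.45% in mitochondrial genes (5.863 to 6.666). In 14-day OVCAR-8 3D 21%, replicate 1 had a TMM factor of 1.031 (0.979 to 0.9803).

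Differences between the lines were flagged by the test of the OVCAR-8 change minus the MCF-7 change. For 3D 21% against 2D at day 7, 6478 genes differed. The gene differences were 3.83 for FRMD4A, 2.9 for UNC13D, 1.82 for RHBDF1, 1.5 for SIN3B, 1.99 for HID1, -4.29 for TAGLN, -3.86 for PARM1, -1.64 for GCNT1, -1.67 for COX6C and -1.15 for GLUD1. For 3% against 21% at day 7, 2778 differed, with 1.51 for ZNF114, 0.83 for HEXB, 1.68 for GCNT2, 1.17 for NUCB2, 1.15 for ARNTL2, -3.37 for AMIGO2, -2.37 for ITGB4, -2.19 for VIPR1, -2.98 for RUNX2 and -2.44 for PNPLA3. For 3D 21% against 2D at day 14, 7885 differed, with 6.49 for STC1, 3.58 for ARRDC3, 3.61 for CAV1, 2.93 for NPNT, 3.64 for NT5E, -8.28 for FOS, -4.55 for SEMA3E, -4.41 for LOXL2, -3.39 for CDC42EP3 and -5.64 for IGFBP3. For 3% against 21% at day 14, 749 differed, with 1.78 for EMP1, 1.2 for ANXA6, 1.88 for ATP6V0A4, 1.07 for SERTAD2, 1.64 for ANKRD37, -1.41 for HLA-B, -4.37 for GJA1, -2.8 for LRRC15, -3.59 for NFKBIZ and -1.19 for PTPRK.

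Splits of the libraries tested whether such counts arise from any grouping. In 7-day OVCAR-8, 1 of 35 splits, the real one, was as large in each comparison, so chance can be excluded: 13028 genes against a highest other of 0 for 3D 21% and 2D, 12559 against 3 for 3% and 2D, 12941 against 0 for gradient and 2D, 7503 against 2 for 3% and 21%, 151 against 81 for gradient and 21%, and 7359 against 295 for gradient and 3%. Only the real split was as large also in 14-day MCF-7 for 3D 21% and 2D (12846 against 0). The same held in 14-day OVCAR-8 for 3D 21% and 2D (8429 against 0) and 3% and 2D (7846 against 3227). It held there too for gradient and 2D (8327 against 0) and gradient and 3% (344 against 131). In 14-day OVCAR-8 for gradient and 21%, 4 of 35 splits were as large (81 against 1124), so the real split does not stand out. A split with several times the real count points to a structure of the samples. In 7-day MCF-7 it can be excluded for 3% and 2D (6687 against 4832), but not for 3D 21% and 2D (3 of 35 splits, 1164 against 4449, again a structure of the samples, the largest having 2D replicates 1 to 3 as one arm) or gradient and 2D (2 of 35, 3128 against 3136). Within 3D in 7-day MCF-7, where the numbers pair the libraries, too few splits part as many pairs (8) to give a share under 0.05. For 3% and 21% the real value was 39 and the highest other of these 0, though 3 of all 35 splits were as large and the largest, with 534, parts fewer pairs. For gradient and 21% the values were 0 and 0 in 35 of 35, and for gradient and 3% 1 and 0. Of 60 splits for the line differences, 3 were as large at day 7 for 3D 21% and 2D (6478 against 7136). The 2 besides the real one kept 1 line's cultures, so this is undecided. For 3% and 21% there, 2 of 60 were as large (2778 against 4126), in splits not keeping to the MCF-7 pairs. The larger kept 1 line's cultures. Only the real one of 60 parting all MCF-7 pairs was as large (2778 against 2067). So it was for 3D 21% and 2D at day 14 (7885 against 6108). Splits also undo each line's own change, so they decide neither.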

How the results depend on the processing

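Leaving out all libraries numbered 4 in 7-day MCF-7 or numbered 1 in 14-day OVCAR-8 was chosen after the results were seen, and the other alternatives before. Of 36 counts of called genes, line differences and shared calls, RLE size factors moved 0 by over 1.5 times, no filter 5, DESeq2 11 and a replicate block 12. No call changed sign, but some uncalled results did. Causes were not tested.

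With DESeq2, 3D 21% against 2D in 7-day MCF-7 gave 2140, 3% against 21% 720 and gradient against 3% 211. Gradient against 21% gave 259 in 7-day OVCAR-8 and 270 in 14-day OVCAR-8, gradient against 3% in 14-day OVCAR-8 712, and the 14-day line difference for 3% against 21% 1143. On simulated counts DESeq2 called 42, 18, 13 and 12 unchanged genes where edgeR called 10, 11, 14 and 3 (7-day and 14-day MCF-7, then OVCAR-8). DESeq2's shared calls were 1400 and 210 between lines at day 7 (3D 21% against 2D, then 3% against 21%) and 1839 and 323 between days of MCF-7. Without a filter, gradient against 3% in 7-day MCF-7 gave 9, gradient against 21% in 7-day OVCAR-8 348, the 7-day line difference for 3% against 21% 1768, and the shared calls of the lines at day 7 481 and 14. Without the libraries numbered 4, 7-day MCF-7 gave 4986, 6993, 1182 and 683 (3D 21% and gradient against 2D, 3% against 21%, gradient against 3%), the 7-day line difference for 3% against 21% 4692, and shared calls 3316 and 293 between lines and 4531 and 493 between days. Without the libraries numbered 1, 14-day OVCAR-8 gave 3618 and 1117 (3% against 21%, gradient against 3%), the 14-day line difference for 3% against 21% 1343, and shared calls 1174 between lines and 1151 between days.

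Same-numbered libraries correlated above 0.1 in every pair only within the 3D cultures of 7-day MCF-7, where the block gave 198 for 3% against 21% and 38 for gradient against 3%. There it also called SYVN1, WWC1 and SLC2A1 in the first and JUNB, LIF, SLC16A1 and SLC2A1 in the second, and changed no other call among the named genes. Elsewhere not all pairs exceeded 0.1, but 1 reached 0.541 (14-day OVCAR-8, gradient and 21%). Of the genes given above with a range there, the block also called SLC2A1 for 3% against 21% in 7-day and 14-day OVCAR-8 and for 3D 21% against 2D in 7-day MCF-7, MKI67 in 14-day OVCAR-8 and VEGFA in 14-day MCF-7 for 3% against 21%, and it did not call CAV1 (3D 21% or gradient against 2D) and OLFML3 (gradient against 2D) in 7-day MCF-7. It gave 2046 for 3D 21% against 2D in 7-day MCF-7, 3769, 410 and 1727 in 14-day OVCAR-8 (3% and gradient against 21%, gradient against 3%), and shared calls of 1288 and 70 (lines, day 7), 1292 (lines, day 14), 1768 and 124 (days of MCF-7) and 1310 (days of OVCAR-8).

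Leaving out 1 library at a time gave these ranges, in the order 3D 21%, 3% and gradient against 2D, 3% and gradient against 21%, gradient against 3%. For 7-day MCF-7 they were 298 to 4545, 5117 to 8894, 1591 to 6155, 0 to 335, 0 to 0 and 0 to 12. For 14-day MCF-7 they were 12346 to 12666, 10525 to 11916, 10059 to 11220, 2159 to 4389, 559 to 1499 and 1981 to 3976, where a culture left with 1 library is assumed to vary like the others. For 7-day OVCAR-8 they were 12682 to 12956, 12170 to 12785, 12650 to 12916, 6729 to 7625, 61 to 245 and 6414 to 7534. For 14-day OVCAR-8 they were 7347 to 8468, 6341 to 7270, 7287 to 7899, 769 to 3189, 30 to 151 and 93 to 420. The line differences for 3D 21% against 2D and 3% against 21% ranged over 5628 to 6906 and 1640 to 3788 at day 7 and over 7283 to 8295 and 246 to 1087 at day 14.

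Among named genes, calls lost and gained were 1 and 63 with DESeq2, 4 and 4 with RLE, 58 and 17 without a filter, 8 and 46 with the block, and 695 and 79 of all left-out-library fits. Of 277 camera calls, 277 held with RLE size factors and 27 with estimated correlation, HIF targets in 14-day OVCAR-8 among them. Depth limits the folds of genes near 0 in 2D, such as CA9 with 0 to 3 counts in the 14-day and OVCAR-8 tables, and n = 2 in 14-day MCF-7 at 3% and in the gradient limits the spread that can be estimated.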

Other observations

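No hypothesis beyond the patterns above was tested, and the lists here were fixed before the data were examined. In 14-day MCF-7, 3D at 21% oxygen against 2D (n = 4 and 4) raised 12 of 22 estrogen receptor targets and lowered 8 (camera adjusted p = 0.165), with SERPINA1, a protease inhibitor, at 4.09 (SE 0.1) and TFF1, a secreted trefoil peptide, at 1.73 (SE 0.07). p53 targets rose in 10 of 24 and fell in 9 (camera 0.667), with the growth factor GDF15 at 4.08 (SE 0.12) and TP53INP1 at 2.04 (SE 0.06). Interferon-stimulated genes rose in 16 of 25 and fell in 2 (camera 0.0319, 0.41 with estimated correlation), BST2, which tethers virus particles, by 1.39. Mitochondrially encoded genes rose in 10 of 13 (camera 0.0013, 0.59 with estimated correlation), MT-CO1 by 1.71 (SE 0.1), and mitochondrial transcripts took 2.544% to 3.104% of the counts in 2D and 5.11% to 6.958% in 3D at 21%. Unfolded protein response genes rose in 9 of 19 and fell in 6 (camera 0.37), stem-like cell markers in 7 and 6 of 13 (camera 0.853), and replication-dependent histones in 6 and 5 of 14. MCF-7 line markers rose in 8 of 15 and fell in 5, fibroblast markers in 2 and 0 of 2, immune cell markers in 2 and 0 of 3 and endothelial markers in 1 and 1 of 3.

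In 7-day OVCAR-8 the same comparison (n = 4 and 4) lowered 15 of 21 immediate early genes and raised 4 (camera adjusted p = 0.00229, 0.378 with estimated correlation), with JUN at -1.32 (SE 0.07). Estrogen receptor targets rose in 5 of 16 and fell in 8 (camera 0.525), p53 targets in 7 and 8 of 22 (camera 0.772) and metallothioneins in 1 and 4 of 5 (camera 0.0637), MT1M by -1.65. At 3% against 21% oxygen in 3D, immediate early genes rose there in 15 of 21 and fell in 1 (camera 7.83e-06, 0.194 with estimated correlation), JUN by 0.51 (SE 0.07). Between gradient and 3% oxygen, fibroblast markers rose in 3 of 3 (camera 0.00161, 0.0331 with estimated correlation) and immune cell markers in 2 of 2, with extracellular matrix genes in 20 of 27, where 2 fell (camera 2.73e-08, 0.161 with estimated correlation), COL1A1 by 1.0 (SE 0.06).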
